A study of Homo sapiens with 4 samples.

How the data were processed

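Total RNA of UMSCC1 cells was profiled 3 days after siRNA transfection on 4 single-colour Agilent arrays, 2 with negative control siRNA and 2 with siRNA against NUP62. Per the labels' protocols, Cy3-labelled cRNA was made from 0.2 ug of total RNA with a low-input amplification kit. Samples were grouped by the condition in their labels, and the series' design text calls the 2 samples of each condition biological replicates.

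The deposited scanner files hold intensity values per spot, made with Agilent Feature Extraction version 11.0.1.1, per the submitters' processing notes and the file headers. Per the file headers, the processed signal used here is a linear intensity after background subtraction and detrending within the array, with no scaling between arrays. The files also hold flags per spot for saturation, for outliers and for signal well above background. All 4 arrays lay on 1 slide and came from 1 scan, so slide and scan date could not differ between groups and no slide block was fitted. A deposited value table of 22299 probes holds the authors' processed values, also as intensity. Each of its columns equalled the processed signal of 1 scanner file divided by 1 number close to that array's 75th percentile, which settled its scale (linear), its centring (none per gene) and its direction (none, since it holds levels). The medians of its columns were 0.246, 0.250, 0.241 and 0.247. Its columns headed control replicate 2 and knockdown replicate 1 matched each other's scanner files and not their own, so that table served only as an alternative, with those 2 columns as headed and, chosen after the data were seen, exchanged. How the table was made is not given in the sources used here.

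Each array held 44495 spots, of which 43118 were not controls and carried 34127 probes, 999 of them in 10 spots. Spots marked as non-uniform or as population outliers were left out, which left 53 probes without a value on at least 1 array. The log2 processed signal was averaged over the spots of a probe, and each array's 75th percentile over the non-control probes was subtracted. Probes were kept if measured on all 4 arrays and well above background on both arrays of at least 1 group, which left 24492. Probes were named through the unversioned accession of the files, matched to the RefSeq transcripts of the GRCh38.p14 gene table. By this match 25771 probes had 1 symbol, 0 had several and 8356 had none; the latter kept the name in the files. The gene table was used for names, gene types and gene lengths, and none of its coordinates are given, because the file headers name another build. Each gene was represented by its probe of highest mean signal, giving 15364 genes with a symbol and 4568 unnamed transcripts. Where other probes of a named gene passed in the opposite direction, this is stated beside it.

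Groups were compared with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes, no intensity trend), two-sided, with Benjamini-Hochberg adjustment over all 19932 features tested and a threshold of 0.05 on the adjusted p. A log2 fold change is the knockdown mean minus the control mean, and errors of fold changes are limma's standard errors. With 2 arrays against 2, an exact permutation test of 1 gene cannot pass that threshold (its smallest two-sided p is 0.333), so the p-values rest on limma's pooled estimate of the spread. A gene not well above background on either array of a group has only a bound there. For such a gene the mean of the brighter group was set against the mean, per array of the dimmer group, of the higher of the gene's own signal and the lowest signal well above background on that array, and the ratio is given as at least that fold.

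Fixed before the data were examined were 19 gene lists with 583 entries, of which 582 matched a current symbol and 555 were tested, and markers of 5 cell types. Lists were tested against all other genes with limma's camera at a preset correlation between genes of 0.01, with an adjustment over the 19 lists. Camera with a correlation estimated from the residuals, camera on ranks, and fry, which asks whether a list's genes move on balance in one direction without comparing them with other genes, were alternatives. The rule for naming genes was also fixed then. It took NUP62, TP63, the 10 genes with a symbol and the highest log2 fold change and the 10 with the lowest among those past the threshold with both knockdown arrays outside the range of both control arrays, and up to 3 members past the threshold from each list, which came to 77 genes with a few that are not reported here. Identifiers without an established gene name were left out of the top 10. Other genes are named as examples of a list or marker group, or were chosen after their values were seen.

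The other alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median, no filter on dim probes, a filter on all 4 arrays, keeping the marked outlier spots, the mean over a gene's probes, every probe on its own, an intensity trend with robust estimation, the replicate number as a block, other thresholds, and leaving out each array in turn. The normexp correction used the median signal of each spot, where the mean had been planned, because the files read here have no mean signal column. Its offset was added before the arrays were scaled. It therefore weighs more on arrays of lower signal, here the knockdown arrays, and raises dim features there.

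The fit was tested on simulated data with the real control means of the comparison of NUP62 knockdown with control siRNA and its replicate spreads, shuffled between genes. Among 19932 simulated genes, 200 were changed. Of those changed 1.41-fold, 17.9% were recovered, of those changed 2-fold 61.2%, and of those changed 4-fold 78.8%, with 5 false calls. These rates belong to a setting with few changed genes, unlike the data, where 58.5% of features passed. In a run that gave every gene its observed log2 fold change, 13079 were called, 55 of them with the wrong sign. A simulated shift of 1 list was found, and 0 of the other lists were called. That run had independent noise per gene and no change outside the shifted list. It therefore does not test false list calls among correlated genes or under wide change.

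Between 72.7% and 76.4% of non-control spots were well above background on each array, and 0 were saturated. The number of arrays limits the precision. Over 782 probes in 10 spots, the median SD between spots of a probe on 1 array was 0.05 to 0.06 on the log2 scale. The median absolute difference between replicate arrays over the same probes was 0.04 in either group, against 0.34 between the group means. Spot noise alone would give 0.018 between means of 10 spots, so replicate arrays differed by more than spot noise.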

Results

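Gene expression was measured in UMSCC1 cells, an established human line from a squamous carcinoma of the head and neck, after transfection with negative control siRNA or siRNA against NUP62. NUP62 encodes a nucleoporin of the central channel of the nuclear pore, the complex through which proteins and RNA pass between nucleus and cytoplasm. The comparison asks which transcripts differ once NUP62 is depleted in a squamous carcinoma cell. There were 2 arrays per condition and 4 in all, each from cells collected 3 days after transfection. The 75th percentile of the processed signal was 885 and 950 on the control arrays and 568 and 643 on the knockdown arrays, and between 72.7% and 76.4% of spots were well above background. Levels are log2 signals relative to that percentile, and every change compares the means of 2 arrays per group, in folds where so stated and otherwise on the log2 scale.

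NUP62 itself fell on both knockdown arrays to 19.9% of its control level, a 5.03-fold lower signal. Its brighter probe, A_24_P322444, read 3.54 and 3.47 on the control arrays and 1.17 and 1.18 on the knockdown arrays, so that the group means were 3.50 ± 0.05 (SD, n = 2) and 1.18 ± 0.0023 (SD, n = 2). The log2 fold change was -2.33 ± 0.05 (SE; limma, adjusted p = 0.0016). The second probe, A_33_P3418010, fell to 29.3% of control, with a log2 fold change of -1.77.

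**Figure D1:**
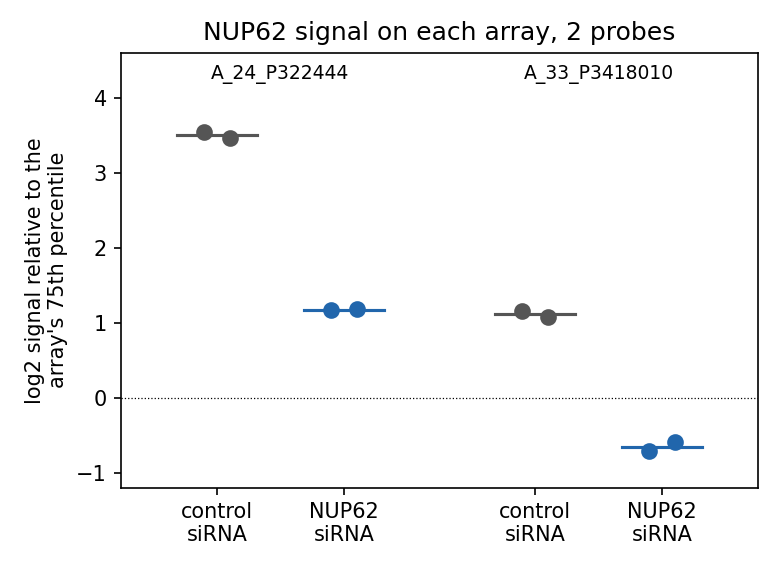
The vertical axis gives the log2 signal of the 2 NUP62 probes relative to the array's 75th percentile, with a point per array, a bar at the group mean, control siRNA in grey and NUP62 siRNA in blue. For probe A_24_P322444 the control arrays sat at 3.54 and 3.47 and the knockdown arrays at 1.17 and 1.18.

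After scaling, a large share of the tested features differed in signal between knockdown and control, mostly by modest amounts. The labels do not give the number or sequence of the siRNAs against NUP62, so off-target effects could not be examined. Of 19932 genes and unnamed transcripts tested with limma, 6627 rose and 5024 fell at an adjusted p under 0.05, together 58.5%. Among those with a gene symbol 4982 rose and 4369 fell. The median size of the change among the called features was 0.54 on the log2 scale, and the smallest was 0.15. Both knockdown arrays were dimmer than both control arrays, and scaling to the 75th percentile removes any change shared by all transcripts. Quantile normalization kept 10804 of the 11651 calls in the same direction. Signal level and condition coincide, so small changes in expression and effects of the dimmer signal cannot be told apart here. Changes of at least 2-fold were found in 744 features that rose and 1071 that fell, and changes of at least 4-fold in 65 and 141. The median log2 fold change of all tested features was 0.11. Arrays of the same condition correlated across probes at r = 0.997 for control and 0.996 for knockdown, and arrays of different conditions at 0.976 to 0.978 (probes are not independent replicates). With normexp background correction 10393 features rose and 4484 fell, so that 69.9% of calls were higher against 56.9% above, and leaving out control replicate 1 gave 3838 and 3283 calls, and control replicate 2 gave 2936 and 2745. The normexp offset is added before scaling, so by itself it raises dim features on the dimmer knockdown arrays. In the deposited value table with its columns as headed limma called 0 features in either direction (76 had an unadjusted p under 0.05). With the columns of control replicate 2 and knockdown replicate 1 exchanged to match their scanner files it called 5563 higher and 3964 lower.

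**Figure D2:**
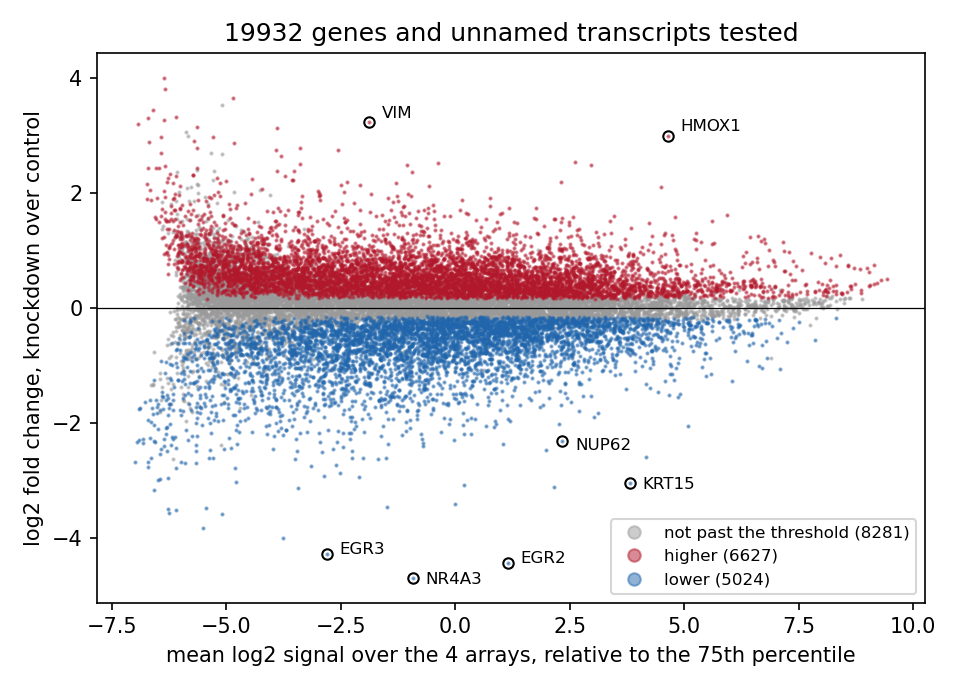
Each point is 1 of 19932 genes or unnamed transcripts, with its mean log2 signal over the 4 arrays on the horizontal axis and its log2 fold change, knockdown over control, on the vertical axis. The 6627 features that rose are red, the 5024 that fell are blue and the 8281 not past the threshold are grey, with 7 genes circled, among them NUP62 at -2.33 and VIM at 3.23.

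The transcription factors NR4A3, EGR2 and EGR3, whose genes respond within minutes to growth factor signals, headed the falling genes. NR4A3 fell by 4.70 on the log2 scale, a 25.9-fold lower signal (SE 0.29; limma, adjusted p = 0.0021). EGR2 fell 21.9-fold, EGR3 19.6-fold, EGR4 10.6-fold and FOSB 8.71-fold, each with an adjusted p of 0.0016 in limma. CH25H, which hydroxylates cholesterol, fell 8.78-fold, and TMT1A, a methyltransferase, fell 8.50-fold. Normexp correction gave smaller log2 fold changes of -3.61 for NR4A3, -2.65 for EGR3 and -1.33 for CH25H, and the exchanged value table gave -3.23 for NR4A3. The other 3 of the 10 genes named for the lowest log2 fold changes were not well above background on either knockdown array, so their rank is uncertain and only a bound is given. IRAG1 was at least 2.997-fold lower, CFI, a complement protease, at least 3.27-fold lower, and MAB21L4 at least 5.07-fold lower. Under normexp correction the fall did not pass for IRAG1 (limma, adjusted p = 0.13) or CFI (0.085) and was 0.39 on the log2 scale for MAB21L4. The MAB21L4 call was lost without control replicate 1 or 2, at log2 fold changes of -3.40 and -3.58. Without control replicate 2 CFI had -1.55. Its probe above, at -4.06 on control replicate 1 and -7.67 and -8.05 on the knockdown arrays, cannot give that value, so another probe represented CFI there.

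VIM, the intermediate filament vimentin of mesenchymal cells, rose 9.38-fold, from -3.50 to -0.27 (log2 fold change 3.23, SE 0.10; limma, adjusted p = 0.0016). HMOX1, the heme oxygenase induced by oxidative stress, rose 7.94-fold from a high control level of 3.15. HBA2, an alpha globin gene, rose 6.88-fold. Under normexp correction VIM rose by 2.45 and HBA2 by 1.73. The other 7 of the 10 genes named for the highest log2 fold changes were not well above background on either control array, so their rank is uncertain and only bounds are given. The cytokines CSF2 and CSF3 were at least 3.74-fold and at least 4.02-fold higher. CREB5 was at least 5.48-fold, GOLGA7B at least 3.57-fold, UGT2A1 at least 2.31-fold and RNF17 at least 1.93-fold higher. A dim probe for CLTC, the clathrin heavy chain, was at least 4.61-fold higher. Normexp correction left these 7 rises at 0.82 to 1.17 on the log2 scale. The call for CSF2 was lost without control replicate 1 or 2, at log2 fold changes of 3.95 and 4.04. RNF17 had 0.49 with no filter on dim probes, 0.14 without control replicate 2 and 1.04 without knockdown replicate 2. Its probe above read -8.60 and -8.44 on the control arrays and -4.79 and -5.85 on the knockdown arrays, which cannot give those values. Another probe represented RNF17 there, so these values show probes that disagree and not a dependence on 1 array.

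**Figure D3:**
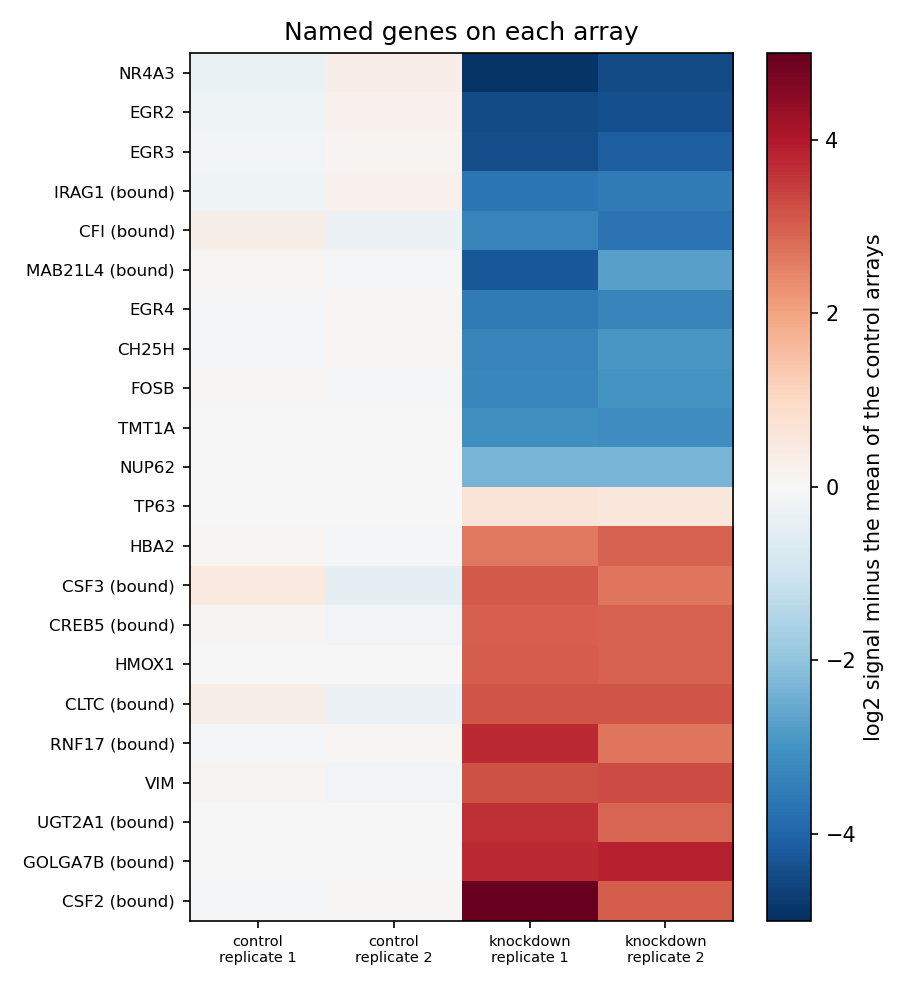
Rows are NUP62, TP63 and the 10 genes named for the highest and the 10 for the lowest log2 fold changes, columns are the 4 arrays, and the colour gives the log2 signal minus the mean of the control arrays. Rows marked as bounds were not well above background in 1 group, where the colour shows the measured value; NR4A3 lies at the top with -4.70 and CSF2 at the bottom.

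TP63, the transcription factor that sets squamous identity, rose 1.52-fold (log2 fold change 0.61, SE 0.05; limma, adjusted p = 0.0032). Of 42 p63 targets and basal squamous genes tested, 16 rose and 16 fell (16 and 16 adjusted over the list alone), and the list did not pass against other genes (limma's camera, adjusted p = 0.38), while fry called it lower (adjusted p = 0.014). KRT15, a keratin of basal keratinocytes, fell 8.27-fold, SOX2, a squamous lineage factor, fell 4.18-fold, and CLCA2 was at least 2.82-fold lower, though under normexp its call was lost (limma, adjusted p = 0.46). The integrin genes ITGA3 and ITGB4, which anchor basal cells, rose by 1.09 and 1.02, while EGFR fell by 0.97 on the log2 scale.

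Genes of epidermal differentiation shifted downward relative to all other genes tested. Of 43 tested, 20 fell and 8 rose (20 and 8 adjusted over the list alone), with a median log2 fold change of -0.33 (limma's camera, adjusted p = 0.0086). That call was lost with an estimated correlation (limma's camera, adjusted p = 0.52), a test with 2 residual degrees of freedom that 0 of 19 lists passed. The correlation estimated for this list was 0.00046, below the preset 0.01. Normexp correction, whose offset raises dim genes on the knockdown arrays, turned the counts to 17 fallen and 17 risen. SPRR2A, a cornified envelope precursor, fell 6.10-fold in its brighter probe and by 1.02 in the other, KRT13, a keratin of stratified mucosa, fell 5.60-fold, and ZNF750, a transcription factor of terminal differentiation, fell 3.76-fold. Filaggrin, FLG, rose by 1.09 and envoplakin, EVPL, by 0.65.

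The genes for other nucleoporins did not pass the threshold as a list against other genes. Of 30 tested, 10 rose and 6 fell (9 and 6 adjusted over the list alone; limma's camera, adjusted p = 0.74), and with arrays scaled to their medians 4 rose and 7 fell. NUP50, a nuclear basket protein, rose 2.05-fold in its brighter probe and by 0.21 in the other, and NUP35 rose 1.71-fold. The brighter probe of AHCTF1, a pore assembly factor, fell by 0.74 and its dimmer probe rose by 0.77. Transport receptors and Ran cycle genes rose in 18 of 30 cases and fell in 3 (19 and 3 adjusted over the list alone), with a median of 0.30 (limma's camera, adjusted p = 0.018). That call had adjusted p = 0.58 with an estimated correlation, and 0.16 under normexp correction. TNPO1, the import receptor transportin, rose 3.01-fold and XPO1, the main protein export receptor, rose 2.36-fold, while IPO9 fell 2.35-fold, or by 0.33 under normexp, a call lost without either control array (limma, adjusted p = 0.062 and 0.065).

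Ribosome biogenesis genes rose in 25 of 30 cases and fell in 1 (25 and 1 adjusted over the list alone), with a median log2 fold change of 0.41 (limma's camera, adjusted p = 0.00018; adjusted p = 0.52 with an estimated correlation). RRP9 rose 1.97-fold, URB2 1.95-fold and UTP20 1.84-fold, all factors of pre-rRNA processing. Genes of G2/M and mitosis fell in 20 of 41 cases and rose in 5 (20 and 5 adjusted over the list alone), with a median of -0.17 (limma's camera, adjusted p = 0.0019; adjusted p = 0.52 with an estimated correlation). HMMR, a spindle assembly factor, fell 1.93-fold, the kinase AURKA fell 1.67-fold, and the spindle motor KIF11 fell 1.64-fold. The 5 risen members were MAD2L1, CDC20, ECT2, FOXM1 and PLK1, by 0.19 to 0.33. Of 45 genes of DNA replication and G1/S, 16 rose and 8 fell (16 and 7 adjusted over the list alone; limma's camera, adjusted p = 0.62). RPA2 rose 1.60-fold and SLBP, which binds histone mRNA, rose 1.57-fold, while E2F2 fell 1.92-fold.

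Targets of p53 went both ways, with 6 of 27 risen and 9 fallen (6 and 9 adjusted over the list alone; limma's camera, adjusted p = 0.38). GDF15, a stress-induced cytokine, rose 3.05-fold, AEN, an apoptosis-enhancing nuclease, rose 2.73-fold and the cell cycle inhibitor CDKN1A rose by 0.70. POLH, a translesion polymerase, fell 2.53-fold. Among 27 apoptosis regulators 9 rose and 7 fell (9 and 7 adjusted over the list alone; limma's camera, adjusted p = 0.91). The death ligand TNFSF10 fell 2.12-fold and the survival gene BCL2L1 rose 1.78-fold. BMF fell by 0.78 in its brighter probe and rose by 1.40 in its dimmer probe, and the fall had adjusted p = 0.0503 in limma without control replicate 2.

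Interferon response genes fell in 19 of 35 cases and rose in 4 (21 and 4 adjusted over the list alone), with a median log2 fold change of -0.35 (limma's camera, adjusted p = 0.00046; adjusted p = 0.58 with an estimated correlation). The correlation estimated for this list was 0.21, above the preset 0.01. The median was -0.12 under normexp correction. OASL fell 7.73-fold, or by 2.04 under normexp, and the GTPase GBP1 fell 3.86-fold. IFI44L was not well above background on either knockdown array, and its bound of 3.20-fold lower was the measured ratio itself. Normexp correction gave it a log2 fold change of 0.02. The signal transducer STAT2 fell by 0.98 on the log2 scale, and IRF7 rose by 0.54. In the list of NF-kB and inflammatory cytokines 13 of 25 genes rose and 7 fell (13 and 7 adjusted over the list alone; limma's camera, adjusted p = 0.44). Besides CSF2 and CSF3, CXCL3 rose by 2.16, TNF by 2.01 and IL24 by 1.74. PTGS2, the inducible cyclooxygenase, fell 6.18-fold, IL1B fell by 1.56 and the inhibitor TNFAIP3 fell by 0.58.

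**Figure D4:**
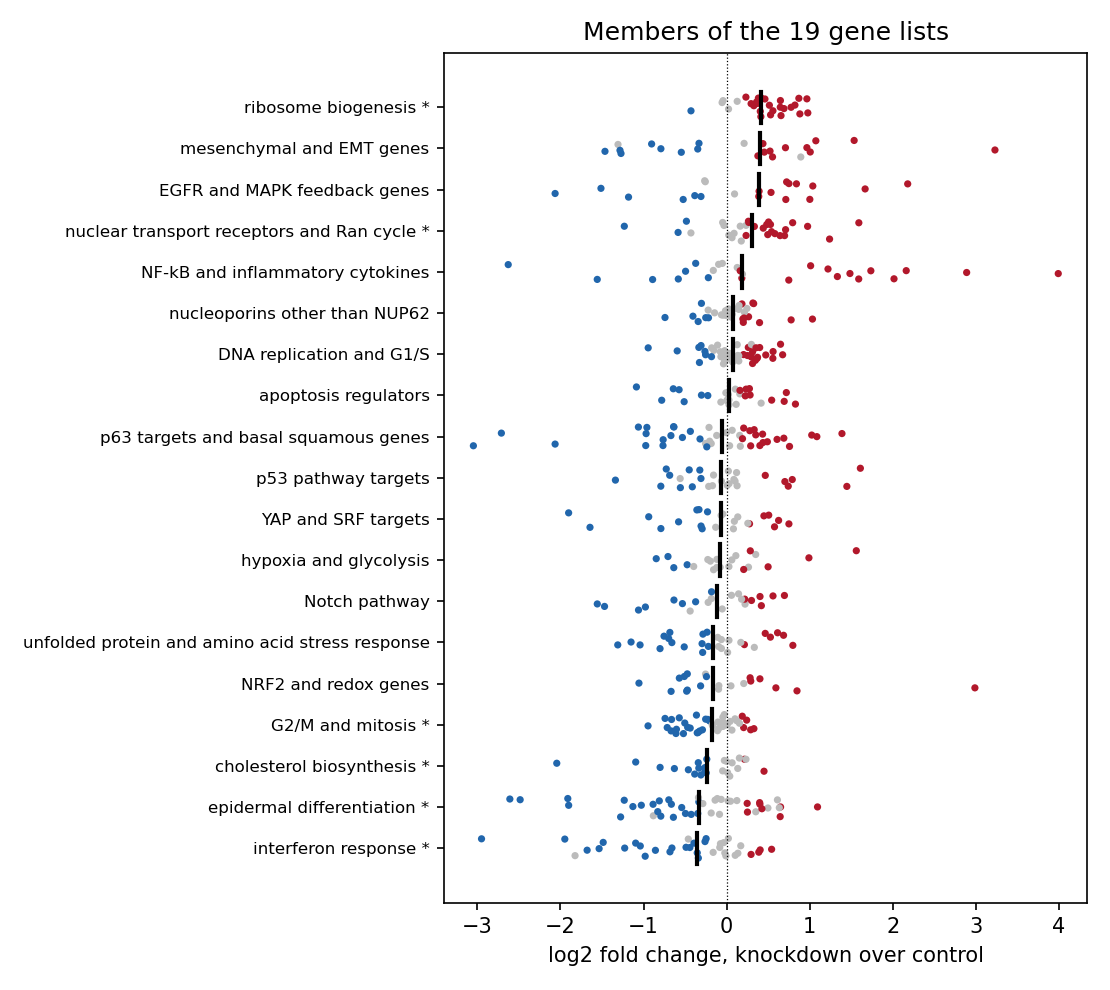
Each row is 1 of the 19 gene lists, each point a tested member at its log2 fold change, knockdown over control, in red where it rose, blue where it fell and grey where it did not pass, and the black bar is the list's median. The 6 lists marked with an asterisk passed limma's camera with the preset correlation, with medians from -0.35 for interferon response to 0.41 for ribosome biogenesis, and 0 lists passed with an estimated correlation.

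Mesenchymal and EMT genes divided, with 11 of 22 risen and 8 fallen (11 and 8 adjusted over the list alone; limma's camera, adjusted p = 0.82). Besides VIM, the transcription factor SNAI1 rose 2.90-fold, and ZEB1 rose by 0.71. The collagen gene COL5A2 fell 2.76-fold and COL1A2 fell by 1.27. Of 28 genes of the unfolded protein and amino acid stress response 14 fell and 6 rose (14 and 7 adjusted over the list alone; limma's camera, adjusted p = 0.051). The endoplasmic reticulum chaperone HSPA5 fell 2.48-fold and HERPUD1 fell 2.06-fold. ATF3 fell 2.22-fold in its brightest probe, with 3 of its 4 probes fallen and the remaining probe risen by 0.60.

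Feedback genes of EGFR and MAPK signalling rose in 11 of 20 cases and fell in 6 (11 and 7 adjusted over the list alone; limma's camera, adjusted p = 0.58). FOSL1, an AP-1 subunit, rose 4.53-fold and the receptor EPHA2 rose 3.18-fold, while EGR1 fell 4.18-fold. In the Notch pathway 6 of 22 genes rose and 8 fell (7 and 8 adjusted over the list alone; limma's camera, adjusted p = 0.41), and the median of -0.12 became 0.04 under normexp. NOTCH3 fell 2.77-fold, HES2, another list member, fell 2.94-fold and NRARP fell 2.09-fold, the HES2 call being lost without either control array (limma, adjusted p = 0.051 and 0.059). The dimmer NRARP probe had a log2 fold change of 0.61 (limma, adjusted p = 0.051). Targets of YAP and SRF fell in 10 of 23 cases and rose in 6 (10 and 7 adjusted over the list alone; limma's camera, adjusted p = 0.38). The smooth muscle actin ACTG2 fell 3.74-fold, or by 0.77 under normexp, CCN2 fell 3.13-fold and SRF itself fell 1.91-fold.

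Of 24 cholesterol biosynthesis genes 13 fell and 2 rose (13 and 4 adjusted over the list alone), with a median of -0.24 (limma's camera, adjusted p = 0.046; adjusted p = 0.58 with an estimated correlation). This list's call was also lost under quantile normalization (0.065), without control replicate 2 (0.084) and without knockdown replicate 1 (0.059). TM7SF2, a sterol reductase, fell 1.74-fold, or by 0.33 under normexp. SC5D fell 4.12-fold, but only 1 knockdown array had it well above background and its call was lost without either control array (limma, adjusted p = 0.13 and 0.12) and with no filter on dim probes (0.066). Normexp gave it a log2 fold change of -0.31. Among 21 genes of hypoxia and glycolysis 5 rose and 4 fell (3 and 4 adjusted over the list alone; limma's camera, adjusted p = 0.62), with a median of -0.08 and a mean of 0.02. VEGFA rose 2.95-fold and ANGPTL4 1.99-fold, the latter with adjusted p = 0.054 in limma without control replicate 2, and the carbonic anhydrase CA9 fell 1.80-fold. NRF2 and redox genes fell in 9 of 20 cases and rose in 6 (9 and 6 adjusted over the list alone; limma's camera, adjusted p = 0.33), with a median of -0.17, a mean of 0.02 and a downward test. The 2 subunits of the glutathione-synthesis enzyme moved apart, GCLC falling 2.08-fold and GCLM rising 1.80-fold, though GCLM had adjusted p = 0.054 in limma without knockdown replicate 2.

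All 8 epithelial markers were well above background on the 4 arrays. Of these 7 rose, among them KRT8 by 1.27, KRT18 by 0.79 and CDH1 by 0.63, and KRT5 fell by 0.32 on the log2 scale. Of 10 fibroblast markers 4 were well above background on all arrays, and COL1A1, COL1A2 and LUM fell by 0.55, 1.27 and 1.29. Of 9 leukocyte markers on the array 8 were well above background throughout, with CD3E, CD79A and MS4A1 risen and CD14 and LCP1 fallen. Endothelial markers were well above background in 2 of 7 cases, VWF and CDH5, and both rose. Melanocyte markers were so in 3 of 4 cases, of which DCT rose by 0.40 and PMEL fell by 1.05.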

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

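The exchange of 2 columns of the value table was chosen after the data were seen. The NUP62 fall passed under every alternative that held the gene, with log2 fold changes from -2.38 to -2.05, and NUP62 has no row among the 22299 probes of the value table used here. The deposited value table with its columns as headed called 0 genes higher and 0 lower (limma; 76 at an unadjusted p under 0.05), and with 2 columns exchanged 5563 and 3964, of which 9434 were among the 10053 calls above that it could test. As headed it also ended the list calls, with adjusted p = 0.48 for epidermal differentiation and 0.31 for ribosome biogenesis, and turned the direction of G2/M and mitosis (0.24), cholesterol biosynthesis (0.27), interferon response (0.63) and transport receptors (0.88). The log2 fold changes it turned were AEN -0.050, AHCTF1 0.14, ATF3 0.11, AURKA 0.017, CCN2 0.13, CLCA2 0.29, CLTC -0.29, CREB5 -0.18, CSF2 -0.91, CSF3 -0.67, GCLM -0.13, GDF15 -0.0025, HERPUD1 0.0054, HMOX1 -0.090, IFI44L 0.029, IRAG1 0.27, KIF11 0.034, MAB21L4 0.67, NOTCH3 0.028, NRARP 0.10, NUP50 -0.077, RNF17 -0.45, SC5D 0.52, SRF 0.057, TM7SF2 0.047, TP63 -0.042, UGT2A1 -0.38, XPO1 -0.027 and ZNF750 0.12. Exchanged, it left epidermal differentiation at 0.0504 and transport receptors at 0.11, gave interferon response a median log2 fold change of -0.12, left NUP50 at 0.21 (limma, adjusted p = 0.057), and turned no direction of a named gene. The values by themselves show that the headings mix arrays of both conditions. Normexp correction, whose offset raises dim genes on the knockdown arrays, gave 10393 genes higher, moved transport receptors to 0.16 and IFI44L to 0.020. The mean over a gene's probes turned AHCTF1 (0.015) and BMF (0.31), whose probes disagree, left NRARP at -0.22 (limma, adjusted p = 0.21), and moved cholesterol biosynthesis to 0.073. Cholesterol biosynthesis also lost its call under quantile normalization (0.065), the filter on all 4 arrays (0.058) and every probe on its own (0.061). With an estimated correlation G2/M, epidermal differentiation and ribosome biogenesis had adjusted p = 0.52, and cholesterol, interferon and transport lists 0.58, where the test has the 2 residual degrees of freedom of the arrays; fry called 14 of 19 lists. Epidermal differentiation had an estimated correlation of 0.00046, below the preset 0.01, so a higher correlation did not end its call. The other lists that lost their calls had estimates above 0.01. These ran from 0.018 for G2/M and mitosis to 0.065 for cholesterol biosynthesis and 0.21 for interferon response. For those lists a higher correlation and the few degrees of freedom cannot be told apart. Apart from the correlation of epidermal differentiation and the value table, the causes were not tested. With the replicate number as a block, 6352 genes were higher and 4636 lower, and deviations of same-numbered arrays correlated at 0.09 across probes. A change of at least 2-fold left 744 and 1071 genes and an adjusted p under 0.01 left 3380 and 3215. Without 1 array in turn, 2936 to 4774 genes were higher and 2745 to 4162 lower, and the cholesterol list had adjusted p from 0.022 to 0.084; fewer arrays leave less power, and the lone array is assumed to vary like the other group. The slide could not be run as a block, since all arrays shared 1. Signal over background limits the dim genes: 394 calls have only a bound.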

Other observations

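The gene groups in this part were put together after the table of all genes had been examined. For 4 of them, and for gene length, the test was set before the values it uses were looked at, and all other tests in this part were chosen after the result was seen. Of 25 heat shock and chaperone genes tested, 22 rose and 0 fell in limma, with a median log2 fold change of 0.79. HSPA6 rose by 2.53, HSPA1A 2.84-fold, HSPB8 by 1.29, DNAJB1 by 1.06 and HSP90AA1 by 0.71. Of the mitochondrial chaperones, HSPD1 rose by 0.37 and HSPE1 had 0.018. Of chaperones in the endoplasmic reticulum, SERPINH1 from this group rose by 0.76 and HSPA5 from another list fell by 1.31. The median of the 21 members not looked at beforehand was 0.75, above 100% of 10000 random lists of matched brightness. Such lists, here and below, draw genes 1 by 1. They ignore correlation between members and do not measure the spread between arrays. The median of the group stayed between 0.72 and 0.74 under quantile normalization, median scaling and normexp correction. A heat shock response may accompany the loss of NUP62. Both groups were transfected with siRNA, so reagent toxicity is shared unless it differed between them, which these arrays do not measure. Off-target effects of the siRNA against NUP62 stay open.

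Feedback inhibitors and targets of TGF-beta signalling rose in 15 of 22 cases and fell in 5 in limma. SKIL rose by 1.73, BAMBI by 1.67, SMAD7 by 1.64 and ID1 by 1.16, whereas SMAD6 fell by 1.08, the receptor TGFBR1 by 0.79 and LTBP2 by 1.73. The 15 members not looked at beforehand had a median of 0.36, above 97.0% of matched lists, so a wider rise is a hypothesis with members on both sides. Targets of the aryl hydrocarbon receptor, with the receptor and its partner ARNT, fell in 8 of 9 cases, although a second probe of TIPARP rose. Among the xenobiotic enzymes CYP1B1 fell by 2.20, CYP1A1 by 2.08, UGT1A6 by 1.97 and ALDH3A1 by 1.66. The 5 members not looked at beforehand had a median of -0.28, and 9.72% of matched lists lay lower, which leaves a fall of the whole pathway undecided.

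Among long non-coding genes a larger share of calls was lower than among protein-coding genes under 3 of 4 treatments of the signal, although the median log2 fold changes of all tested were close, at 0.059 and 0.063. Of 538 long non-coding genes tested, 186 fell and 140 rose, so that 57.1% of their calls were lower, against 46.5% for protein-coding genes and 45.0% for protein-coding genes of the same brightness, a difference of 12.04 percentage points. The shares were 62.2% against 50.7% under quantile normalization and 60.9% against 52.4% with median scaling, but 29.95% against 36.5% after normexp correction. That alternative also started from another signal column, and its offset raises dim features on the dimmer knockdown arrays. The long non-coding genes were dim, with a median level of -3.40 against -0.39 for protein-coding genes. The turn under normexp correction can therefore follow from the offset and does not decide the question. A fall of long non-coding transcripts and an effect of signal processing on dim probes therefore cannot be told apart here. Gene length had no such relation, with a Spearman's rho of -0.015 between genomic length and log2 fold change across 14427 protein-coding genes, which are not independent replicates.

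The fall of immediate-early genes was uneven. Of 37 tested, 23 fell and 7 rose in limma, with a median of -0.55, although 16 of them were chosen after their values were seen. The median of the 37 stayed at -0.58 under quantile normalization, -0.60 with median scaling and -0.56 after normexp correction. The 95% bootstrap intervals over members ended at -0.18 or lower, so these treatments did not remove the fall of this set. The set holds the 16 members chosen after their values were seen, so its median could hardly rise, and median scaling shifts all genes alike. Scaling and brightness of the probes therefore stay undecided for the class. The cytokine and chemokine genes, which also have short-lived mRNA, had a median of 1.01 (95% bootstrap interval over 17 genes 0.13 to 1.74). They were picked after the result was seen from the 25 tested NF-kB and inflammatory genes, whose median was 0.18. The pick left out PTGS2, which fell by 2.63, and mRNA stability was not measured. A general loss of short-lived transcripts therefore stays open. Weaker ERK signalling stays open, since 8 ERK feedback genes had a median of 0.57 with an interval from -0.31 to 1.00. The 21 members not looked at beforehand had a median of -0.084, with 7.88% of matched lists lower, and JUN falling by 1.13 and IER2 by 1.06 while ARC rose by 1.19. A fall of the whole class stays undecided, and so do harvest conditions, which these genes answer to within minutes and which are not given in the labels.

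More features rose than fell at the threshold, most of all among the dimmest, though at 2-fold or more 1071 fell and 744 rose. In the dimmest 20% of tested features 67.0% of calls were higher. The share was 57.5%, 51.9% and 52.3% in the next classes of rising brightness and 60.1% in the brightest 20%. With arrays scaled to their medians 51.2% of all calls were higher, but that scaling itself moves the median log2 fold change from 0.11 to 0.055, so the choice of scaling factor stays open. Under quantile normalization 46.7% of calls in the dimmest 20% were higher, while normexp correction raised that share to 99.3%. For the dimmest 20%, an effect of brightness and a true rise of weak transcripts cannot be told apart here, because quantile normalization removes both.

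In the deposited value table, the column headed control replicate 2 matched the scanner file of knockdown replicate 1 in 98.0% of probes within 0.001 on the log2 scale, after division by 1 factor, and the column headed knockdown replicate 1 matched control replicate 2 in 98.3%. Each matched its own scanner file in 0.135% and 0.117%. An exchange of the 2 headings is consistent with this. Exchanged scanner files are argued against by NUP62 itself, since the file labelled control replicate 2 read -0.076 relative to control replicate 1 and 2.29 above knockdown replicate 2. No biological explanation was tested for this pattern.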
